A study of Homo sapiens with 12 samples.

How the data were processed

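RNA sequencing of mRNA from total RNA was analysed for 12 libraries of sorted KG1a cells, 3 in each of 4 groups: normoxic dim, normoxic bright, hypoxic dim and hypoxic bright, hypoxia being 3% oxygen. Dim and bright refer to the surface level of CD38 and CLL-1 on CD34-positive cells. Per the submitters' processing notes, paired-end reads were trimmed with Trimmomatic 0.39 and aligned to hg38 with STAR 2.4.2a. The tool that counted the reads, its annotation and the strand of counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty.

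The deposited values are a score per gene and library, which the authors made by dividing read counts by a median-of-ratios size factor per library and rounding to whole numbers. This was read from the values: the median ratio of each library to the gene-wise geometric mean lay between 1.00303 and 1.00422, and whole numbers were missing or doubled at regular steps. The spacing of these steps gave the value of 1 read, between 0.815 and 1.27 normalized units, and so an estimated depth of 25200000 to 39500000 counted reads per library. On 12 simulated libraries this estimate was off by at most 3.5%. Because the values were normalized and rounded, a test for raw counts, which had been chosen for the case that the table held counts, was not used. Of 28395 genes in the table, 330 had no symbol, 27 symbols had been turned into dates by a spreadsheet and were read by gene ID, and 97.7% of gene IDs were matched to a RefSeq table.

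Log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a mean trend), with a mean for each of the 4 groups over all 12 libraries, leaving 8 residual degrees of freedom. Genes with a value of at least 10 in at least 3 libraries were tested (15057), and 13338 were not. The 5 comparisons were bright against dim in normoxia and in hypoxia, hypoxia against normoxia in dim and in bright cells, and the difference of the hypoxia effect between bright and dim cells. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, 2-sided. Folds are those of the fitted log2 values, and standard errors are the moderated ones of limma. A gene was called replicate-discordant when its replicates in any group differed more than 4-fold after 10 was added to each value, which held for 791 tested genes.

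25 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and at an estimated correlation, and with fry, with adjustment over the lists within a comparison. Adjusted p-values of lists are those of camera with the preset correlation unless stated. Each list's genes were counted over all genes tested and also adjusted over the list alone. The comparisons, tests, lists, named genes and most alternatives were chosen before the data were examined. Named were the sort markers, the 6 genes per direction with the largest fitted change among passing genes with a mean of at least 100 in the higher group, replicates that did not overlap between the groups and an ordinary symbol, and up to 2 members per list and direction with the smallest adjusted p. For the difference of effects, only the largest changes were named, and replicates had to be apart in dim or in bright cells. The rule does not name ABCB1, ABCC2, AZU1, BNIP3, BNIP3L, CD74, CDK6, COL1A2, DPYSL3, FAM30A, FTH1, FTL, LMO2, LYL1, NCAM1, PTGDS, S100A4, SLC16A3, SLC2A3, TRIB3 and VEGFA, and these, like genes given in a comparison other than the one that named them, were chosen after their values were seen. Marker lists of skeletal muscle, airway epithelium, neutrophil granules and melanocytes were added after the data were examined.

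The calling of changes was tested on simulated data with 200 changed genes. Noise was drawn independently for each gene, with no shift shared by the genes of a library. The false calls given here therefore do not describe data with such shifts. At a true 2-fold change 61.2% of changed genes were recovered for bright against dim in normoxia, 62.7% in hypoxia, 70.1% for hypoxia in dim cells, 61.2% in bright cells and 53.7% for the difference, with 2 to 10 false calls. At a 4-fold change between 77.3% and 95.5% were recovered.

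Alternatives chosen before the data were examined were another rescaling, limma without the trend, no filter, a filter at a mean of 50, only the groups compared, the replicate number as a block, pseudocounts of 0.1 and 10, a test against a 1.5-fold change, an adjusted p under 0.01 and leaving out each library in turn. Added afterwards were leaving out replicate-discordant genes or the pair of libraries highest in a marker list, the sums of 3 marker lists as covariates on the raw and on the log2 scale, removal of the trend with gene length or GC content, and a count of list calls by fry in place of camera.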

Results

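KG1a is an established human cell line from acute myeloid leukaemia with an immature, CD34-positive phenotype. CD34 and CD38 are surface molecules used to grade the maturity of such cells, and CLL-1, encoded by CLEC12A, is a lectin receptor of myeloid cells. The samples were KG1a cells sorted into CD34-positive cells dim for CD38 and CLL-1 (called dim) and CD34-positive cells bright for both (called bright). Each subset came from normoxia or from hypoxia at 3% oxygen. RNA sequencing of mRNA gave 12 libraries, 3 in each of 4 groups, and the question was how oxygen affected both subsets. The normalized values summed to between 31828256 and 32560463 per library, and the spacing of the whole numbers put the reads counted at an estimated 25200000 to 39500000. Between 17167 and 18684 genes had a value above 0 in a library, and 15057 genes were tested. Values below are normalized values, and errors are standard errors of the log2 fold change unless given as SD, with n = 3 in every group. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples.

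Of the sort markers, CD38 was higher in the bright subset, CD34, for which both subsets were positive, was also higher there, and CLEC12A, which was low in all groups, passed no test. CD38, an enzyme that consumes NAD (chromosome 4, 15778298 to 15849083, hg38), had a mean of 5.0 ± 2.65 (SD) in normoxic dim and 69.7 ± 11.2 in normoxic bright libraries. In hypoxia its means were 15.7 ± 8.33 and 142 ± 18.2. The bright to dim log2 fold change of CD38 was 3.67 ± 0.42 in normoxia (adjusted p = 0.000118) and 3.21 ± 0.42 in hypoxia (adjusted p = 0.000249). CD34 (chromosome 1, 207881028 to 207911338) was abundant in every library and was 1.53-fold higher in bright cells in normoxia and 1.71-fold higher in hypoxia. CLEC12A (chromosome 12, 9951316 to 9999354) had group means between 13.3 and 21 with log2 fold changes of -0.48 ± 0.58 in normoxia and 0.10 ± 0.58 in hypoxia. These errors leave a small difference in CLEC12A transcript open, but not one of the size seen for CD38. In hypoxia its sign turned without hypoxic dim replicate 2 (-0.33), hypoxic dim replicate 3 (-0.04) or hypoxic bright replicate 1 (-0.29).

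**Figure D1:**
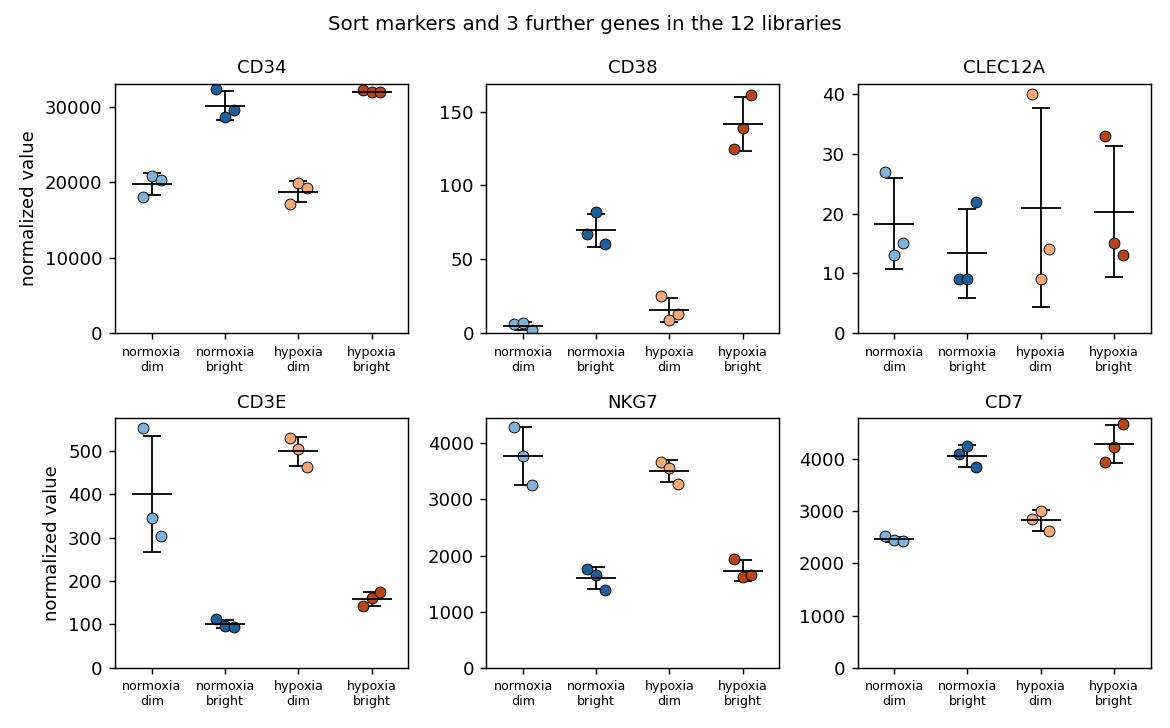
Normalized values of 6 genes in the 12 libraries, on linear axes from 0. Points are libraries, horizontal lines are group means and bars are SD (n = 3). CD38 lies between 60 and 161 in the 6 bright libraries and between 2 and 25 in the 6 dim libraries, whereas CLEC12A overlaps in all groups.

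The first comparison asked how bright cells differed from dim cells in normoxia. Dim cells had higher values of 19 of 34 interferon-response genes, 15 of 28 DNA replication genes and 6 of 14 lymphoid markers, and bright cells of 13 of 29 mitosis genes. With an estimated correlation the interferon list passed (adjusted p = 0.0319) and the others did not (adjusted p = 0.064, 0.139 and 0.208). All of these lists passed with fry (adjusted p = 8.73e-05, 0.000216, 0.000641 and 0.00863). Bright cells also had more of NYNRIN, of the megakaryocyte integrin ITGA2B, of the chemokine receptor CCR2 and of the transcription factors GATA2 and EPAS1. The lymphocyte chemokine XCL2 was 9.96-fold lower in bright cells, with a mean of 58.3 against 611 in dim cells, and NYNRIN (chromosome 14, 24398786 to 24419288) was 2.84-fold higher, with means of 1262 and 443. With limma, 433 genes were higher and 570 were lower in bright cells, and 26 of the higher genes differed more than 4-fold between replicates of a group.

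Among the largest falls from dim to bright in normoxia were those of PRSS2 (log2 fold change -4.04 ± 0.35), COL21A1 (-3.72 ± 0.38), XCL1 (-3.64 ± 0.42), FGFBP2 (-3.41 ± 0.20), the integrin subunit ITGB7 (-3.41 ± 0.28) and XCL2 (-3.32 ± 0.24). XCL1 and XCL2 are nearly identical, as are PRSS2 and other trypsinogen genes, so the split of reads within each family is uncertain. Of 14 lymphoid markers, 6 were lower, 1 was higher and 7 did not pass, and 9 were lower adjusted over the list alone (camera, adjusted p = 7.78e-05, and adjusted p = 0.139 with an estimated correlation). The T cell receptor chain CD247 fell by 2.35 ± 0.22, NKG7 of cytotoxic granules fell by 1.23 ± 0.12, and CD3E had a mean of 101 against 400 in dim cells. CD7 was the marker that was higher (0.72 ± 0.08). Of 34 interferon-response genes, 19 were lower and 15 did not pass, and 25 were lower adjusted over the list alone (adjusted p = 1.31e-18). This was the list call that held with an estimated correlation (adjusted p = 0.0319). The guanylate-binding protein GBP1 fell by 1.61 ± 0.12.

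Cell cycle genes moved apart in normoxia. Of 28 DNA replication genes, 15 were lower in bright cells and 25 were lower adjusted over the list alone, with the replication licensing factors CDC6 at -0.51 ± 0.06 and MCM6 at -0.38 ± 0.06 (adjusted p = 1.12e-17, and adjusted p = 0.064 with an estimated correlation). Of 29 mitosis genes, 13 were higher and 17 were higher adjusted over the list alone, with cyclin CCNB2 at 0.70 ± 0.10 and the centromere histone CENPA at 0.64 ± 0.08 (adjusted p = 3.91e-14, and adjusted p = 0.208 with an estimated correlation). Of 24 genes of the unfolded protein and integrated stress response, 4 were lower, among them ATF3 (-1.38 ± 0.22) and PPP1R15A (-0.67 ± 0.09), and 6 were lower adjusted over the list alone (adjusted p = 7.78e-05, and adjusted p = 0.167 with an estimated correlation). Among 25 stem and progenitor genes, GATA2 (0.70 ± 0.08), FLI1 (0.40 ± 0.07), LMO2 and LYL1 were higher, while 6, including HOXA10 (-0.54 ± 0.09) and EMCN (-0.88 ± 0.15), were lower. Adjusted over the list alone 8 were higher and 6 lower, and the list passed no test of a common direction (adjusted p = 0.813), its median being 0.06 and its mean -0.20. Of the 17-gene leukaemia stem cell score, whose genes were chosen in patients for their link to outcome, CD34 and NYNRIN were higher and DNMT3B (-0.29 ± 0.08) and EMP1 (-1.99 ± 0.41) were lower (adjusted p = 0.0275 upward, and adjusted p = 0.319 with an estimated correlation). The genes were tested as a list, and the score itself was not computed.

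Single myeloid and adhesion genes differed between the subsets. Of 24 granulocyte and monocyte genes, CD33 (1.2 ± 0.22) and the transcription factor SPI1 (1.7 ± 0.35) were higher in bright cells, while the proteoglycan VCAN (-2.70 ± 0.14) and CEBPB (-0.49 ± 0.09) were lower, with 3 in each direction adjusted over the list alone (adjusted p = 0.212). Of 20 adhesion and homing genes, 4 were lower, among them PECAM1 (-1.02 ± 0.10), and CCR2 was higher (1.44 ± 0.18), with 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.0525). ICAM1 was lower (-1.35 ± 0.13) as 1 of 5 lower and 4 higher among 20 inflammatory genes, with 6 lower and 5 higher adjusted over the list alone (adjusted p = 0.631). EPAS1, which encodes an oxygen-regulated transcription factor, was the member of 9 oxygen-sensing components that was higher (1.23 ± 0.16), with means of 1015 and 428. The drug efflux gene ABCB4 was higher (1.12 ± 0.29), and of 40 ribosomal protein genes RPS2 was higher (0.33 ± 0.08). The ribosomal list and the 35 oxidative phosphorylation genes, which had medians of 0.13 and 0.08, passed upward with camera (adjusted p = 2.94e-06 and 0.00272, and adjusted p = 0.604 for both with an estimated correlation).

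Among the largest rises from dim to bright in normoxia were those of CEACAM6 (6.67 ± 1.54), MUC5B (6.60 ± 1.78), CYP24A1 (6.42 ± 1.41), KRT18 (5.93 ± 1.39), CPLX2 (5.75 ± 1.49) and ALDH3A1 (4.83 ± 1.23), all of which differed more than 4-fold between replicates of a group. MUC5B, a secreted mucin of airways, had values of 812, 1606 and 37 in the 3 normoxic bright libraries and between 0 and 8 in the normoxic dim libraries. The summed value of 15 airway epithelium markers was 3712, 7463 and 365 in these bright libraries and between 206 and 315 in normoxic dim. The count of 1003 genes became 613 without normoxic dim replicate 1, 640 without normoxic dim replicate 3 and 645 without normoxic bright replicate 2. More genes were higher than lower without the libraries highest in granule genes (605 higher, 558 lower). The count was 584 without the libraries highest in airway epithelium markers, 629 without those highest in skeletal muscle markers and 134 with the log2 sums of 3 marker lists as covariates.

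The next comparison put bright against dim cells in hypoxia. Bright cells again had more CD38, CD34 and NYNRIN and higher values of 13 of 29 mitosis genes, and dim cells had higher values of 7 of 14 lymphoid markers, 18 of 34 interferon-response and 17 of 28 DNA replication genes. With an estimated correlation these lists did not pass (adjusted p = 0.411, 0.363, 0.321 and 0.313), whereas with fry they did (adjusted p = 0.0436, 0.00212, 0.00111 and 0.000368). Bright cells also had more of several hypoxia-inducible transcripts, and lower values of 17 of 24 stress response genes and 7 of 13 mitochondrially encoded transcripts (adjusted p = 0.172 and 0.411 with an estimated correlation). The stress response and mitochondrial lists passed with fry (adjusted p = 6.29e-05 and 0.0257). NYNRIN was 4.82-fold higher in bright cells (means 1920 and 396), VCAN was 4.13-fold lower (means 233 and 963), and the collagen prolyl hydroxylase subunit P4HA1 was 2.11-fold higher (means 2871 and 1308). With limma, 1941 genes were higher and 2053 lower. Of the 433 genes higher in bright cells in normoxia, 297 were also higher in hypoxia where independent lists would share 55.8, and of the 570 lower genes 386 were also lower (77.7 for independent lists). Another 36 genes were higher in normoxia and lower in hypoxia, where independent lists would share 59. Over all tested genes the effects in normoxia and in hypoxia had a Pearson correlation of -0.11, genes not being independent replicates, and 0.21 without replicate-discordant genes. It was -0.25, -0.012 and -0.070 without normoxic dim replicates 1, 2 and 3, -0.0053, -0.063 and -0.21 without normoxic bright replicates 1, 2 and 3, and -0.040 without hypoxic dim replicate 2. These comparisons share no library.

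Among the genes with the largest rises in hypoxia were CD38, the lymphocyte receptor CD84 (2.51 ± 0.31), CTTNBP2 (2.48 ± 0.24), the transcription factor IKZF2 (2.44 ± 0.32), IGSF9B (2.41 ± 0.29) and LINC01336 (2.31 ± 0.27). CIITA, the regulator of HLA class II genes, was higher at a low level (means 83.0 and 9.33). Of 22 glycolysis and glucose uptake genes 7 were higher in bright cells, including HK2 (0.86 ± 0.12) and PFKL (0.42 ± 0.08), and ALDOC and PFKM were lower. Adjusted over the list alone 10 were higher and 2 lower (adjusted p = 0.00584, and adjusted p = 0.511 with an estimated correlation). Of 34 other hypoxia-inducible genes 13 were higher, including P4HA1 (1.08 ± 0.18) and the histone demethylase KDM4B (0.58 ± 0.08), and 6 were lower, including CXCR4 (-3.22 ± 0.75) and CA9 (-5.48 ± 1.34). Adjusted over the list alone 13 were higher and 8 lower, and this list passed no directional test (adjusted p = 0.0963), with a median of 0.15 and a mean of -0.39. CA9 and CXCR4 differed more than 4-fold between replicates. Of 20 JmjC histone demethylases, which use oxygen as a substrate, 9 were higher, among them KDM5B (0.82 ± 0.08), and JMJD6 and RIOX2 were lower. Adjusted over the list alone 9 were higher and 3 lower (adjusted p = 0.00542, and adjusted p = 0.363 with an estimated correlation).

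Of the 24 stress response genes 17 were lower in hypoxic bright than in hypoxic dim cells and 20 were lower adjusted over the list alone, including ATF3 (-1.90 ± 0.22), TRIB3 (-1.21 ± 0.17) and PPP1R15A (-0.82 ± 0.09), at adjusted p = 4.29e-08 (adjusted p = 0.172 with an estimated correlation). Of 23 immediate early and heat shock genes 12 were lower and 13 adjusted over the list alone, including JUN (-1.08 ± 0.22), at adjusted p = 0.00143 (adjusted p = 0.332 with an estimated correlation). Of 13 mitochondrially encoded transcripts 7 were lower and 9 adjusted over the list alone, including ND1 (-0.51 ± 0.10) and ND2 (-0.70 ± 0.11), at adjusted p = 0.000218 (adjusted p = 0.411 with an estimated correlation). Of 35 oxidative phosphorylation genes 10 were lower in both counts, including COX7C (-0.49 ± 0.09), at adjusted p = 0.00143 (adjusted p = 0.464 with an estimated correlation). DNA replication genes were lower in 17 of 28 members, and in 22 adjusted over the list alone (adjusted p = 9.45e-08, and adjusted p = 0.313 with an estimated correlation). Mitosis genes were higher in 13 of 29, and in 15 adjusted over the list alone (adjusted p = 8.44e-05, and adjusted p = 0.411 with an estimated correlation). Interferon-response genes were lower in 18 of 34 members in both counts, with GBP1 at -0.92 ± 0.12 and MX1 at -0.84 ± 0.15 (adjusted p = 0.000249, and adjusted p = 0.321 with an estimated correlation). Of 14 lymphoid markers 7 were lower, including CD3E (-1.65 ± 0.19) and NKG7 (-1.02 ± 0.12), and CD7, NCAM1 and PAX5 were higher. There were 9 lower and 3 higher adjusted over the list alone (adjusted p = 0.0294, and adjusted p = 0.363 with an estimated correlation).

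Of the 17-gene stem cell score, 7 genes were higher in hypoxic bright cells, among them CDK6 (0.76 ± 0.13) and FAM30A (0.78 ± 0.12), and EMP1, BEX3 and DPYSL3 were lower. There were 9 higher and 4 lower adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.332 with an estimated correlation), with a median of 0.28 and a mean of -0.27. These genes were tested as a list, and the score itself was not computed. Among drug efflux genes ABCB4 (1.99 ± 0.29), ABCB1 (0.64 ± 0.12) and ABCC1 (0.53 ± 0.09) were higher and ABCG2 (-1.35 ± 0.32), ABCC2 and ABCC3 were lower. Of 24 granulocyte and monocyte genes 10 were lower and 12 adjusted over the list alone, while CD33 (1.48 ± 0.22) and ANPEP (0.21 ± 0.07) were higher in both counts (adjusted p = 0.018, and adjusted p = 0.49 with an estimated correlation). The lower ones included VCAN (-2.05 ± 0.14), CEBPB (-0.83 ± 0.09) and the neutrophil granule proteins ELANE, PRTN3 and AZU1. PRTN3 was 7043 in hypoxic dim replicate 1 and 23 and 92 in replicates 2 and 3, and the summed value of 6 neutrophil granule genes was 17765 in that replicate and between 53 and 59 in the hypoxic bright libraries. Among the largest falls were those of GABRE (-6.85 ± 0.68), IGF2BP1, PRTN3, SLC7A2, NCS1 and ELANE, all of genes that differed more than 4-fold between replicates, as did 278 of the 2053 lower genes. Airway epithelium markers summed to 1320, 19333 and 5997 in the hypoxic dim libraries and to 324, 1227 and 78 in hypoxic bright. The count of 3994 genes became 2627 without hypoxic dim replicate 2, 2468 without hypoxic bright replicate 1 and 2291 without hypoxic bright replicate 2. More genes were higher than lower without hypoxic dim replicate 2 (1324 higher, 1303 lower) and without hypoxic bright replicate 1 (1269 and 1199). The count was 2309 without the libraries highest in airway epithelium markers, and 611 and 44 with 3 marker sums or their log2 values as covariates.

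**Figure D2:**
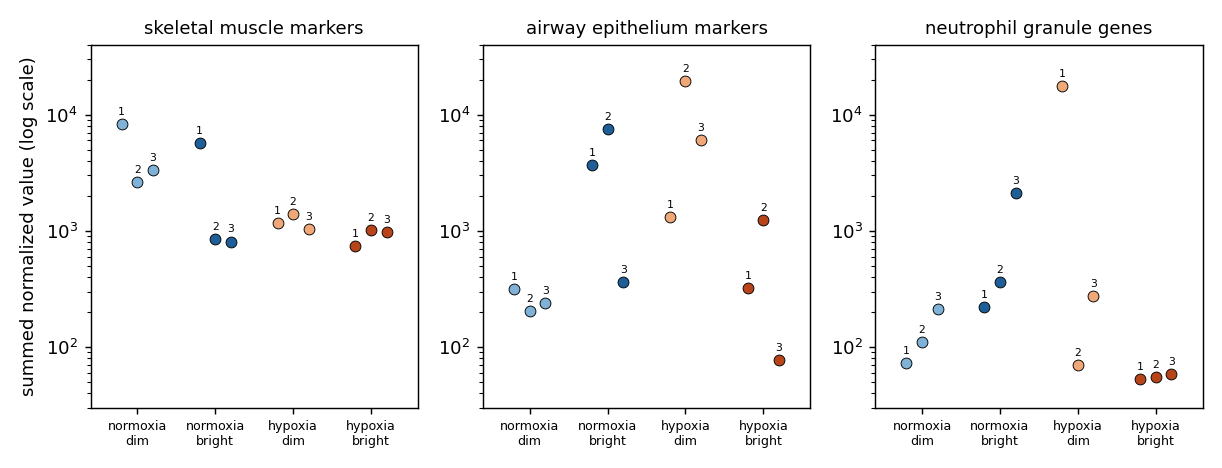
Summed normalized values of 3 marker lists in the 12 libraries, on log axes. Points are libraries, and the small digits are replicate numbers. Granule genes sum to 17765 in hypoxic dim replicate 1, and airway epithelium markers to 19333 in hypoxic dim replicate 2.

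The third comparison asked what 3% oxygen did to dim cells. The transferrin receptor TFRC (chromosome 3, 196049284 to 196082161), which takes up iron, was 2.08-fold lower in hypoxia, with means of 18302 and 37558 (log2 fold change -1.05 ± 0.15, adjusted p = 0.0165). The interleukin-33 receptor IL1RL1 fell by 1.10 ± 0.17 and HEG1 fell by 0.85 ± 0.16. The calcium-binding protein S100A4 rose by 0.90 ± 0.16, from 665 to 1256. With limma, 30 genes were higher and 5 lower in hypoxia.

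The lists of hypoxia-inducible genes did not pass in dim cells. With limma, 0 of 22 glycolysis and 0 of 34 other hypoxia-inducible genes passed, and at unadjusted p under 0.05 the counts were 1 higher and 1 lower, and 5 higher. Adjusted over the list alone, 0 and 4 were higher (camera adjusted p = 0.372 and 0.0577). MIR210HG, the host transcript of a hypoxia-induced microRNA, had means of 36.3 and 131, and BNIP3 differed by 0.17 ± 0.21, P4HA1 by 0.08 ± 0.18 and LDHA by 0.15 ± 0.10, none of which passed. Of 40 ribosomal protein genes 0 passed with limma over all genes, 28 were higher at unadjusted p under 0.05, and 20 were higher adjusted over the list alone, with a median of 0.21 (camera adjusted p = 1.68e-14, and adjusted p = 0.625 with an estimated correlation). Of 35 oxidative phosphorylation genes 14 and of 13 mitochondrially encoded transcripts 7 were higher at unadjusted p under 0.05, and 7 and 0 adjusted over the list alone. Their medians were 0.16 and 0.27 (adjusted p = 4.88e-07 and 4.43e-05, and adjusted p = 0.625 for both with an estimated correlation). Across all tested genes the log2 fold change in dim cells had a Spearman correlation of -0.291 with gene length, and log2 values relative to the mean of all libraries had correlations with length of -0.174, -0.275 and -0.0625 in the hypoxic dim libraries.

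Among the largest rises in dim cells were those of KRT18 (7.69 ± 1.39), the basement membrane collagen COL4A5 (6.14 ± 0.84), SDC1 (5.12 ± 0.92), CYP2S1 (5.07 ± 0.73), GABRE (4.99 ± 0.68) and SPINT1 (4.86 ± 0.90), all with means of 7.0 or less in normoxic dim libraries. Of these KRT18, CYP2S1, GABRE and SPINT1 differed more than 4-fold between replicates of a group. TNFAIP2 rose by 4.43 ± 0.63, from 36.7 to 766. Across the 30 higher genes the median log2 fold change between hypoxic and normoxic bright cells was -2.56 (quartiles -3.45 and -1.07), 25 of the values being negative. Of these genes 10 were among the 54 that fell in bright cells, where independent lists would share 0.108. Airway epithelium markers summed to 1320, 19333 and 5997 in the hypoxic dim libraries and to between 206 and 315 in normoxic dim. The count of 35 genes was 0 without hypoxic dim replicate 2 and 635 without hypoxic dim replicate 3, 54, 1 and 1 without normoxic dim replicates 1, 2 and 3, 131 and 15 without normoxic bright replicates 1 and 2, and 10 without hypoxic bright replicate 1. More genes were lower than higher without hypoxic dim replicate 3 (300 higher, 335 lower) and without normoxic bright replicate 1 (53 higher, 78 lower). With 3 marker covariates in either form, or without the libraries highest in airway epithelium markers, it was 0, and at an adjusted p under 0.01 it was 1.

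The fourth comparison asked what 3% oxygen did to bright cells. Several transcripts known to be induced by hypoxia rose. MIR210HG (chromosome 11, 565657 to 568457) rose 9.76-fold, from a mean of 42.3 to 448 (log2 fold change 3.29 ± 0.34, adjusted p = 0.00138). The mTOR inhibitor DDIT4 (chromosome 10, 72273919 to 72276039) rose 2.62-fold, the glycolysis regulator PFKFB4 3.32-fold, and the sialic acid receptor SIGLEC6 3.22-fold (means 558 and 1849). TFRC fell by 0.77 ± 0.15 and the chemokine CXCL8 fell by 1.18 ± 0.24. With limma, 72 genes were higher and 54 lower in hypoxia.

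Of 34 other hypoxia-inducible genes 8 rose and 26 did not pass, and adjusted over the list alone 13 rose and 2 fell. They were MIR210HG, ANKRD37 (1.5 ± 0.32), DDIT4 (1.39 ± 0.20), the mitophagy receptors BNIP3 (1.29 ± 0.21) and BNIP3L (1.08 ± 0.17), P4HA1 (1.18 ± 0.18), the angiogenic factor VEGFA (0.67 ± 0.10) and the demethylase KDM3A (0.61 ± 0.10). The list passed upward (adjusted p = 1.41e-07, and adjusted p = 0.397 with an estimated correlation). Of 22 glycolysis and glucose uptake genes 4 rose, and adjusted over the list alone 14 rose and 1 fell (adjusted p = 6.48e-10, and adjusted p = 0.397 with an estimated correlation). The 4 were PFKFB4, the glucose transporter SLC2A3 (0.67 ± 0.14), the lactate transporter SLC16A3 (0.69 ± 0.15) and lactate dehydrogenase LDHA (0.50 ± 0.10). PIK3R6 rose by 1.98 ± 0.28, NYNRIN by 0.60 ± 0.13, SMIM24 by 0.44 ± 0.08 and the interferon-induced OAS2 by 0.53 ± 0.11. OAS2 was the member of the interferon list that passed, 2 rose adjusted over the list alone, and the list passed upward with a median of 0.10 (adjusted p = 0.00192, and adjusted p = 0.397 with an estimated correlation).

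Of the 24 stress response genes 0 passed in bright cells with limma over all genes, 9 were lower at unadjusted p under 0.05 and 8 were lower adjusted over the list alone, with a median of -0.20 (adjusted p = 7.98e-07, and adjusted p = 0.316 with an estimated correlation). Immediate early and heat shock genes had a median of -0.32, mitochondrially encoded transcripts of -0.21 and oxidative phosphorylation genes of -0.09 (camera adjusted p = 5.05e-05, 0.000942 and 0.000449). With an estimated correlation their adjusted p = 0.397, 0.549 and 0.549. Among the largest falls were those of SERPINA3 (-5.24 ± 1.02), USP22 (-4.91 ± 0.95), IGF2BP1 (-4.75 ± 1.00), PLS3 (-4.57 ± 0.93) and CST3 (-4.28 ± 0.69), all of genes that differed more than 4-fold between replicates. TNFAIP2 fell by 3.69 ± 0.63. In the hypoxic bright libraries MIR210HG was 652, 471 and 222 and P4HA1 was 3865, 2803 and 1945, each above the highest normoxic library. The count of 126 genes was 7 and 39 without hypoxic bright replicates 1 and 2, 55, 35 and 75 without normoxic bright replicates 1, 2 and 3, 265, 73 and 219 without hypoxic dim replicates 1, 2 and 3, and 45 without normoxic dim replicate 3. The majority turned without normoxic bright replicate 3 (29 higher, 46 lower), hypoxic dim replicate 1 (124 higher, 141 lower) and hypoxic bright replicate 2 (17 higher, 22 lower). The count was 11, 51 and 355 without the libraries highest in airway epithelium, skeletal muscle or granule markers, and 4 with the log2 marker sums as covariates.

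**Figure D3:**
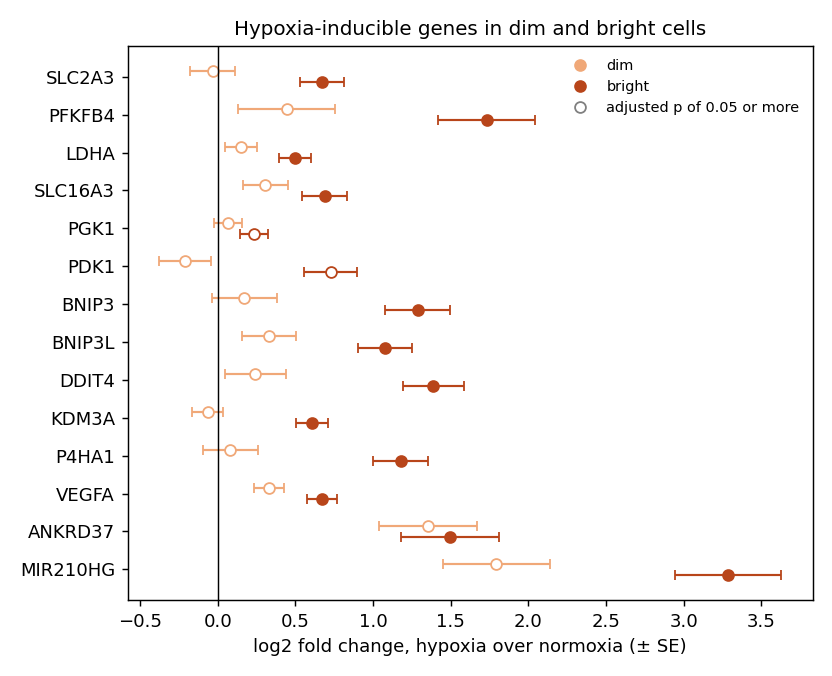
Log2 fold change from normoxia to hypoxia of genes of the 2 hypoxia lists in dim and in bright cells, chosen for plotting after their values were seen. Bars are standard errors (n = 3 in every group), and open points did not pass. MIR210HG, DDIT4 and P4HA1 passed in bright cells and in no case in dim cells.

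The last test asked whether hypoxia acted differently on bright and dim cells. The response of P4HA1, DDIT4 and KDM3A was larger in bright cells, with differences in log2 fold change of 1.10 ± 0.25, 1.14 ± 0.28 and 0.67 ± 0.14. For MIR210HG the difference was 1.49 ± 0.48 and did not pass (adjusted p = 0.103). OAS2 (0.68 ± 0.15) also differed upward. With limma, 165 genes had a more positive and 190 a more negative response in bright cells, and 95 of the latter differed more than 4-fold between replicates. The difference is also that of the bright to dim contrast between hypoxia and normoxia.

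Among the largest positive differences were those of IGSF9B (2.15 ± 0.41), SIGLEC6 (1.83 ± 0.26), the aminopeptidase LNPEP (1.71 ± 0.36), ANKRD36C (1.66 ± 0.32), ZNF699 (1.66 ± 0.29) and ZBED6 (1.62 ± 0.34). ANKRD36C has close copies and ZBED6 lies inside another gene, so their reads are uncertain. Among the largest negative differences were those of MUC5B (-11.12 ± 2.51), KRT18 (-10.83 ± 1.97), COL4A5 (-10.67 ± 1.18), GABRE (-10.61 ± 0.96), CYP24A1 (-10.50 ± 1.99) and CEACAM6 (-9.98 ± 2.18), genes whose means were lower in normoxic dim and hypoxic bright than in the other groups. Glycolysis genes had a median difference of 0.28, with 0 passing over all genes with limma, 10 higher at unadjusted p under 0.05, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000462, and adjusted p = 0.519 with an estimated correlation). The other hypoxia-inducible genes had a median of 0.25 and a mean of -0.30, with 3 higher over all genes, and 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.528 with an estimated correlation). Across all tested genes the response in dim and in bright cells had a Pearson correlation of -0.37, genes not being independent replicates. It was -0.51 and -0.28 without normoxic dim replicates 1 and 2, and -0.50 and -0.23 without normoxic bright replicates 1 and 2. The count of 355 genes was 651, 68 and 72 without normoxic dim replicates 1, 2 and 3, 635 and 55 without normoxic bright replicates 1 and 2, 69 and 1516 without hypoxic dim replicates 2 and 3, and 44 and 127 without hypoxic bright replicates 1 and 2. The majority became positive without normoxic dim replicate 1 (350 higher, 301 lower), normoxic bright replicate 1 (383 and 252), hypoxic dim replicate 3 (781 and 735) and hypoxic bright replicate 3 (186 and 149), and without replicate-discordant genes (231 and 130). The count was 5 without the libraries highest in airway epithelium markers, 1 and 0 with the marker covariates (sums and log2 sums), 43 without the trend and 187 with the gene length trend removed (43 higher, 144 lower).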

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

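The tests of other cells' RNA, of depth, of a response of dim cells alone and of granule genes below were chosen after the results were seen, and those of gene length, GC content and other splits of the samples before.

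The response to hypoxia differed between bright and dim cells for 355 genes by a limma test of the difference itself. Among them it was more positive in bright cells for IGSF9B (2.15), SIGLEC6 (1.83), LNPEP (1.71), ANKRD36C (1.66), ZNF699 (1.66) and ZBED6 (1.62). It was more negative for MUC5B (-11.12), KRT18 (-10.83), COL4A5 (-10.67), GABRE (-10.61), CYP24A1 (-10.50) and CEACAM6 (-9.98), all log2 differences. The fitted changes of KRT18, COL4A5 and GABRE were 7.691, 6.139 and 4.989 in dim cells and -3.135, -4.534 and -5.625 in bright cells. MUC5B, KRT18, GABRE, CYP24A1 and CEACAM6 differed more than 4-fold between replicates of a group. Without single libraries the count of 355 genes lay between 44 (hypoxic bright replicate 1) and 1516 (hypoxic dim replicate 3). It was 651, 68 and 72 without normoxic dim replicates 1, 2 and 3, 635 and 55 without normoxic bright replicates 1 and 2, 69 without hypoxic dim replicate 2 and 127 without hypoxic bright replicate 2. With the marker sums or their log2 values as covariates the count was 1 and 0. It was 5 without the libraries highest in airway epithelium markers and 43 without the trend.

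The test of the difference also passed for 11 gene lists with the preset correlation. Their median differences were 0.279 for glycolysis and glucose uptake, 0.246 for other hypoxia-inducible genes (mean -0.301), 0.249 for interferon response, 0.194 for JmjC histone demethylases (mean -0.0495) and 0.185 for adhesion and homing (mean -0.0295). They were -0.286 for oxidative phosphorylation, -0.456 for mitochondrially encoded transcripts, -1.02 for granulocyte and monocyte differentiation, -0.235 for the stress response, -0.188 for immediate early and heat shock genes and -0.23 for ribosomal proteins. With an estimated correlation none of the 11 passed, the adjusted p lying between 0.496 and 0.528, and with fry 0 lists passed.

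The 30 genes higher in hypoxic than in normoxic dim cells, led by KRT18 and COL4A5, were weighed first. The estimated depth differed 1.00-fold between the groups and the genes by a median of 16-fold. Libraries of an estimated 25200000 to 39500000 reads could not have differed 16-fold, so this test could not have come out in favour of depth. In bright cells the median of these genes was -2.56 (quartiles -3.45 and -1.07), with 25 of 30 values negative. As a set they therefore did not change in dim libraries alone, although S100A4 (0.083) and KIFC3 (0.045) hardly moved in bright cells. If RNA of other cells raised the normoxic bright values, this median cannot decide on a response of dim cells. RNA of other cells cannot be told apart from other causes: the 3 marker sums explained 65.4% of the within-group variance of 29 of these genes, at percentile 97.1 of 10000 random lists, but 49.5% and percentile 70.7 with log2 sums. A candidate source is airway epithelium, whose marker list was added after the data were examined. The highest of its 15 markers in hypoxic dim replicate 2 were MUC5B, KRT8 and KRT18, at 5209, 4162 and 4099. ST14 and SFTPB were at 8 and 0 in that library. The cells had been sorted as CD34-positive, and whether such RNA or reads entered after the sort was not tested. Of the 15 markers 9 had a mean of 10 or more in hypoxic bright libraries, 2 reached 10 in every library and 4 stood in another list. Their sums were 1320, 19333 and 5997 in hypoxic dim replicates 1, 2 and 3. KRT18 (506, 4099 and 1781) and LAMA5 (666, 2145 and 834) had the same order. COL4A5 (164, 205 and 102) and GABRE (384, 201 and 78) did not, being lowest in replicate 3. Of the 30 genes 8 differed more than 4-fold between replicates of a group.

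The larger number of genes that differed between bright and dim cells in hypoxia than in normoxia, a ratio of 3.98, was weighed next. A trend with gene length or GC content as the whole cause is argued against, since the ratio was 3.35 and 3.73 with these trends removed. Without replicate-discordant genes it was 3.62, but it was 0.827 and 0.328 with the marker sums and their log2 values as covariates, so RNA of other cells cannot be told apart from a wider difference in hypoxia. With these covariates the median standard error in hypoxia rose from 0.131 to 0.206 and 0.301. The median absolute log2 fold change of the genes called as fitted went from 0.533 to 0.489 and 0.558. Absolute values hide changes of sign and grow with noise, so these medians do not show whether the calls ended through the wider error. An effect of oxygen on the difference between the subsets stays open.

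As a sum, neutrophil granule genes were high in hypoxic dim replicate 1 (17765) and normoxic bright replicate 3 (2113). CTSG, a member of this list, was not raised. It was at 15 and 18 in these libraries, against means of 15 and 25 in the other replicates of their groups, and the ratios below leave it out. A single source diluted to both levels cannot be told apart from separate sources: the background-subtracted ratios of 5 genes between these libraries differed 7.58-fold (6.41 to 48.6), and 3.96-fold without subtraction, but 1.87-fold without MPO. MPO was also at 28 and 178 in the other normoxic bright libraries, so its background is uncertain, and the error of at most 8.69% covers counting only. Maturation of some of the sorted cells stays open too, since 25 stem and progenitor genes had a median log2 ratio to the other replicates of -0.186 in hypoxic dim replicate 1 (lower quartile -0.419) and -0.00321 in normoxic bright replicate 3, and a small share of matured cells would move these abundant genes little. What brought these transcripts was not found.

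For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 1003, 3994, 35 and 126, against 0 for the highest other split in all of them. Every other split mixes both real groups in each relabelled group, so a real difference enters the spread and lowers the calls. The 0 calls therefore do not show that the grouping is real. For the difference of effects 1 of 100 splits drawn, the real one, gave 355 genes or more, and the highest other gave 127. This excludes nothing for the difference of effects, because splits of all 12 libraries mix the bright to dim difference into the spread within groups and so give fewer calls by design.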

How the results depend on the processing

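The alternatives with marker sums, left-out library pairs, replicate-discordant genes, length and GC were chosen after the results were seen, as was counting the calls of fry, itself a test chosen before, in place of those of camera. The cause of a change was not tested unless stated. Counts are given in the order normoxia bright against dim, hypoxia bright against dim, hypoxia in dim, hypoxia in bright, and difference of effects, where all moved by more than 1.5 times. A test against a 1.5-fold change gave 108, 269, 7, 3 and 81 genes and an adjusted p under 0.01 gave 477, 1901, 1, 20 and 30, both by construction stricter. The log2 marker sums as covariates gave 134, 44, 0, 4 and 0, and without the 2 libraries highest in airway epithelium markers the counts were 584, 2309, 0, 11 and 5. The raw marker sums gave 611 for hypoxia bright against dim, 0 for hypoxia in dim and 1 for the difference, with 739 and 150 for the others.

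Without the libraries highest in skeletal muscle markers the counts were 629 in normoxia, 220 for hypoxia in dim, 51 in bright and 1017 for the difference, and without those highest in granule genes 158, 355 and 542 for the last 3. Without the trend these were 9, 31 and 43. The stricter filter gave 12 for hypoxia in dim and 164 for the difference, and no filter gave 70 for hypoxia in bright. With only the groups compared, hypoxia in dim gave 13 and in bright 226. A pseudocount of 0.1 gave 12 for hypoxia in dim, and one of 10 gave 22, 60 and 162 for hypoxia in dim, in bright and the difference. With the GC trend removed these were 120, 491 and 1390, and with the length trend removed the difference was 187. With the replicate number as a block hypoxia in dim gave 60 genes and the other counts stayed within 1.5 times (917, 3782, 162 and 329), and 55 of 56 list calls were shared. The labels do not say that a number marks a shared culture or day. Of 18 same-number pairs 7 correlated over 0.1, which is short of all pairs, and 7 of 12 libraries correlated best with a library of their own number. The highest of these correlations was 0.448, between the replicate 1 libraries of normoxic dim and normoxic bright, which are the libraries highest in skeletal muscle markers (8321 and 5747). In the replicate 2 libraries normoxic bright and hypoxic dim correlated at 0.444, hypoxic dim and bright at 0.32 and normoxic and hypoxic bright at 0.196, and these are the libraries highest in airway epithelium markers in their groups (7463, 19333 and 1227).

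The larger direction changed too. For normoxia bright against dim it was 605 higher and 558 lower without the granule-high libraries. For hypoxia bright against dim more genes were higher than lower with the stricter filter (1888 and 1659), an adjusted p under 0.01 (981 and 920), raw and log2 marker sums (351 and 260, 23 and 21), and without replicate-discordant genes (2016 and 1862) or the epithelium-high libraries (1169 and 1140). For hypoxia in dim more genes were lower than higher without the muscle-high libraries (76 higher, 144 lower). For hypoxia in bright this held with the block (72 and 90), raw marker sums (72 and 78), only the groups compared (110 and 116), a test against a 1.5-fold change (1 and 2) and without the granule-high libraries (91 and 264). For the difference it was 1 higher and 80 lower against a 1.5-fold change and 43 and 144 with length removed, but 109 and 55 with the stricter filter, 605 and 412 without the muscle-high libraries and 231 and 130 without replicate-discordant genes.

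Leaving out each library in turn gave 613 to 1281, 2291 to 4341, 0 to 635, 7 to 265 and 44 to 1516 genes, and 47 to 61 list calls. Over 125 list tests camera made 56 calls, 1 with an estimated correlation, and 51 with genes of 2 or more lists left out. The test fry made 27 calls (9, 16, 1, 1 and 0 by comparison, in the order above). Not all were among the 56: adhesion and homing in normoxia, for example, had an adjusted p of 0.00218 with fry and 0.0525 with camera. The correlation across genes of the hypoxia effect in dim and in bright was -0.62 with genes that passed in neither left out and -0.51 to -0.23 without single libraries. That of the bright to dim effect in normoxia and in hypoxia was -0.11, -0.25 to -0.0053 without single libraries, and turned to 0.21 without replicate-discordant genes. Genes are not independent replicates.

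Of the named genes that passed, 14 of 51 in normoxia, 4 of 78 in hypoxia, 0 of 11 for hypoxia in dim, 1 of 20 in bright and 0 of 12 for the difference passed under every alternative run. The low CLEC12A turned sign most often. In normoxia it was 0.019 without the muscle-high libraries. In hypoxia it was -0.022 with marker covariates, -0.33 without the epithelium-high libraries, and -0.33 to 0.68 without single libraries. From normoxia to hypoxia in dim it was 0.033 with a pseudocount of 10, 0.29 with marker covariates, 0.43 without the epithelium-high and 0.29 without the muscle-high libraries, 0.038 with GC removed, and -0.59 to 0.43 without single libraries. With log2 marker covariates CD34 turned to 0.057 in dim and -0.049 in bright from normoxia to hypoxia, EPCAM to 0.60 and PFKM to 0.10 for hypoxia bright against dim, and KRT18 to 0.74 for the difference. With the length trend removed CD34 in dim was 0.016. The values of 1 read, 0.815 to 1.27, limit statements on small differences of genes near 10 such as CLEC12A.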

Other observations

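Tests in this part were chosen after the values were seen. No list of iron genes was fixed or tested, and the genes here were singled out after their values were seen. TFRC was lower in hypoxia in dim cells (-1.05 ± 0.15) and in bright cells (-0.77 ± 0.15), with means of 37558, 18302, 28101 and 16401 in normoxic dim, hypoxic dim, normoxic bright and hypoxic bright libraries. TFRC was the gene that passed as lower in both subsets. Of 30 alternatives it did not pass in 10 for dim cells and in 15 for bright cells. Its log2 fold changes there were -1.25 to -0.51 and -1.20 to -0.68. The ferritin chains FTH1 and FTL were lower in bright than in dim cells, FTH1 by a log2 fold change of -0.56 ± 0.11 in normoxia (adjusted p = 0.00866) and -0.76 ± 0.11 in hypoxia (adjusted p = 0.000639). FTL differed by -0.54 ± 0.09 (adjusted p = 0.00283) and -0.78 ± 0.09 (adjusted p = 0.000129). VWF was higher in hypoxic bright than in hypoxic dim cells (1.44 ± 0.16, means 797 and 299).

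The genes whose response to hypoxia was more positive in bright cells had a median length of 8646 bases, against 3680 for those more negative and 3496 for the rest. Genes higher in bright than in dim cells in hypoxia had a median length of 5377 bases and lower ones 2844. Mitochondrially encoded transcripts took 6.66% ± 0.621 (SD, n = 3) of the values in hypoxic dim, 5.23% ± 0.162 in hypoxic bright, 5.61% ± 0.588 in normoxic dim and 5.82% ± 0.835 in normoxic bright libraries.

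Skeletal muscle markers summed to 8321, 2622 and 3307 in the normoxic dim libraries, to 5747, 852 and 809 in normoxic bright, and to between 740 and 1389 in the hypoxic libraries. COL1A2 was at 2538 and PTGDS at 1135 in normoxic dim replicate 1. Melanocyte markers summed to 236 and 121 in normoxic bright replicates 1 and 2 and to between 7 and 49 elsewhere. CD74 was at 1290 in hypoxic dim replicate 1 and at 188 in normoxic bright replicate 3, the libraries high in granule genes, and at most 24 in the others.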
